A study of Homo sapiens with 96 samples.

How the data were processed

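Single cells of 2 groups were measured: 53 induced pluripotent stem cells (iPSC) of the established human line 201B7, and 43 neural progenitor cells (NPC) made from that line over 11 days, per the labels. Each library came from 1 cell and was made with a commercial RamDA-seq kit, which reads full-length total RNA, and was sequenced on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.4 and Subread 1.6.4, with the human build GRCh38; the parameters of the alignment are not given in the sources used here.

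The deposited values are estimated counts of read pairs per gene (expected counts), made by the authors with featureCounts 1.6.4 on the GENCODE 32 annotation, per the file headers. The counting shared a fragment with several mapping places or several overlapping genes out in fractions, and no strand option was set, per the file headers. Reads of paralogs, pseudogenes and multigene families, such as POU5F1, NANOG and TDGF1 with their pseudogenes, the replication-dependent histones and the ribosomal protein genes, are therefore split between copies, and their levels are uncertain. Without strand, reads of a gene and of its antisense partner cannot be separated. Among others, this concerns NR2F1 and NR2F1-AS1, FEZF1 and FEZF1-AS1, and EMX2 and EMX2OS. It also concerns TDGF1 and LRRC2, which overlap on opposite strands. Of all values above 0, 38.05% were not whole numbers. They were rounded to whole counts, which moved the total of a cell by 4.51% at most and by 0.0104% in the median cell. The table of the whole series was checked against the files of single cells, and the largest difference was 0. No 2 cells held identical values.

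The files hold 60668 gene IDs, of which 60340 (99.46%) matched a gene symbol. Biotypes came from GENCODE 44, and coordinates are those of the deposited files on GRCh38. Genes on the Y chromosome, XIST and TSIX were left out of gene results.

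Cells are not replicates, and the labels name no separate cultures, so each group counts as 1 sample. No test between groups was made, and no p-value, standard error or number of differing genes is given. Counts were summed over the cells of a group and divided by the group's total, scaled to a total of 1000000 (CPM). The exact Poisson interval (95%) of a sum covers counting error only, since amplified reads without molecular identifiers are not independent molecules. Ratios are NPC over iPSC on the log2 scale with no pseudocount. A group with no reads of a gene was set to 3 counts of its sum, which makes the ratio a bound, and no ratio was formed where both groups had 3 counts or fewer. Members of a gene list entered with at least 1 CPM in 1 group, and are called higher or lower at 2-fold. The median ratio of a list was set against 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries.

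Because depth was very uneven, the mean over cells of the CPM of each cell, every cell weighted equally, is the second weighting. The ratio or mean by equal weights is given beside a summed value where it moves the ratio by more than 1.5-fold. For shares of cells and genes per cell, each cell was thinned to 70000 reads at random, which left out 5 iPSC and 1 NPC with fewer. At that depth 1 read is worth 14.3 CPM. Shares carry exact Clopper-Pearson intervals (95%). Doublets were not called, since each library is described as 1 cell. Leiden clusters used log2(CPM + 1) of the 2000 most variable genes, 10 principal components, 10 neighbours and resolution 1. A cluster was to be named only with 3 or more fixed markers.

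Named genes were set by size before the data were examined. They are the 12 protein-coding genes per direction with the largest ratio at 20 CPM or more in the higher group and a read in 50% of its cells at the thinned depth, the 5 long noncoding RNA genes per direction at 10 CPM or more by the same rule, up to 4 members per list with the largest ratio, and 20 fixed genes. The 36 gene lists, covering cell types, signalling, metabolism, cell cycle and RNA classes, were also fixed before the data were examined. Other members named in the text stand as examples of their list and were chosen after their values were seen. Some named genes are not reported here.

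Alternatives were equal weights per cell, a library size without mitochondrial and ribosomal RNA genes, TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, leaving out shallow cells, thinning, 2 other filters on low genes, a pseudocount of 1 CPM, and leaving out the cell with the most reads of each gene. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and R 4.3.3.

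The procedure was tested on simulated data with the depths of all real cells and 200 genes set apart by known factors. Levels and spread between cells were taken from the iPSC for both groups. The genes followed were protein-coding at 20 CPM or more in iPSC. Lower genes, other RNA classes and the spread of NPC were therefore not covered. Of 50 genes set 4-fold apart, 88% came out at least 2-fold apart in the right direction. For 50 genes set 16-fold apart the share was 100%. Of 7584 genes without a difference, 19.98% came out at least 2-fold apart with summed reads and 6.09% with equal weights, out of 7784 genes in that step. The median log2 ratio of these unchanged genes was −0.30 by summed reads. That is near the shift of −0.33 set by the reads of the raised genes, so the rates hold this shift besides sampling. A 2-fold difference of a single gene is therefore within what sampling of cells and such a shift give together. Of the same genes, 0.171% came out at least 16-fold apart.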

Results

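Human iPSC of the 201B7 line and NPC derived from them were profiled one cell at a time by RamDA-seq, a full-length method that also captures RNA without a poly(A) tail. The NPC had spent 11 days in an induction medium that inhibits SMAD signalling, the route by which BMP, Nodal and TGF-beta ligands act. The series holds 53 iPSC and 43 NPC libraries of 1 cell each. The iPSC libraries summed to 524062010 counts, with a median of 1799869 per cell and a range from 4038 to 107322373. The NPC libraries summed to 205022995, with a median of 1383436 and a range from 58385 to 31172940. The deepest 10 cells held 81.2% of all iPSC counts and 81.6% of all NPC counts, so summed values mainly reflect those cells. Each group is 1 sample with no replicates, and all differences given here describe these libraries. Cells of the same depths were simulated with the spread of iPSC, and protein-coding genes at 20 CPM or more in iPSC were followed. Of those without a difference, 19.98% came out at least 2-fold apart by summed reads and 0.171% at least 16-fold apart. These rates include a shift set by the reads of raised genes. For genes of that level, 2-fold differences of single genes therefore lie within sampling of cells and such a shift, and lower genes were not covered. Intervals cover counting error only, except the limits of the slopes on depth near the end, which come from drawing cells.

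**Figure D1:**
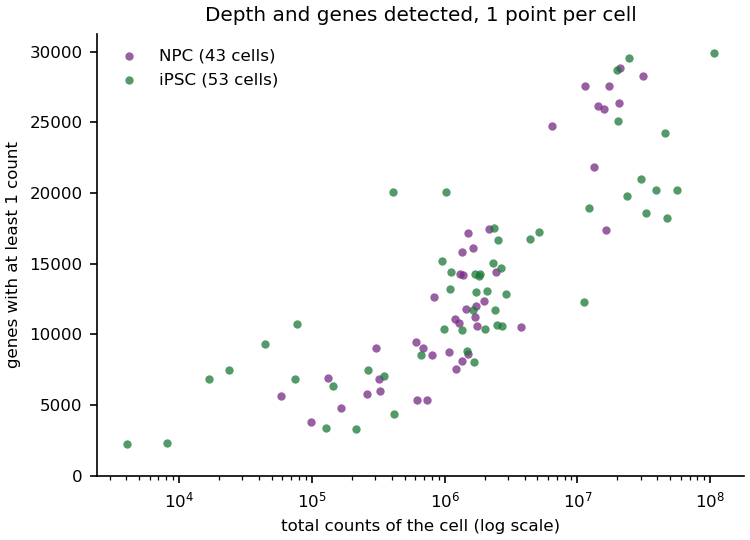
Total counts of each cell (x axis, log scale) against the number of genes with at least 1 count (y axis), for 53 iPSC and 43 NPC. Median totals were 1799869 in iPSC and 1383436 in NPC, and genes detected ranged from 2256 to 29877.

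The first question was whether NPC had left the pluripotent state. Transcripts of the core pluripotency factors were almost gone from NPC. POU5F1 (ENSG00000204531.18, chromosome 6, 31164337 to 31180731 on GRCh38), a transcription factor that maintains pluripotency, stood at 1496 CPM in iPSC (95% Poisson interval 1493 to 1500) and at 2.18 CPM in NPC (1.98 to 2.39), a log2 ratio of −9.43. NANOG, its partner, was at 212 and 1.43 CPM, with a log2 ratio of −7.22. With every cell weighted equally the NPC means were higher, at 10.4 CPM for POU5F1 and 2.68 CPM for NANOG, against 1256 and 159 CPM in iPSC, and the log2 ratios were −6.91 and −5.89. SOX2, which serves both pluripotent and neural cells, was at 166 and 135 CPM, with a log2 ratio of −0.30 that became −1.05 under TMM scaling. Of 20 pluripotency genes, 17 were at least 2-fold lower in NPC, 0 were higher and 3 lay within 2-fold, whereas all 20 were lower under TMM scaling. Their median log2 ratio was −5.83, or −4.41 with equal weights and from −6.90 to −3.36 over all alternatives, and 0 of 10000 matched random lists had a median as low.

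Pluripotency genes did not all share the low NPC level. The de novo DNA methyltransferase DNMT3B was at 2311 CPM in iPSC and 63.9 CPM in NPC, a log2 ratio of −5.18, or −4.41 with equal weights. The RNA-binding protein LIN28A, a regulator of let-7 microRNA, still stood at 595 CPM in NPC against 2076 CPM in iPSC. SALL4 was at 353 CPM in NPC and 570 CPM in iPSC, and LIN28B at 78.1 and 107 CPM. SALL4, LIN28B and KLF4 were the 3 members within 2-fold by total counts. Among protein-coding genes at 20 CPM or more in iPSC and read in at least 50% of these cells at 70000 reads, the 12 with the largest ratios towards iPSC were TMEM125, RAB20, HTR7, RAB17, LRRC2, LAD1, TDGF1P3, PRDM14, ZFP42, TDGF1, ZSCAN10 and GAL, with log2 ratios from −10.19 to −9.58. Weighting cells equally brought these ratios to between −7.88 for RAB20 and −5.53 for TMEM125. TDGF1, a Nodal co-receptor, was at 643 CPM in iPSC and 0.815 CPM in NPC, or 620.2 and 7.07 CPM with equal weights. Its copy TDGF1P3 shares reads with it, so their separate levels are uncertain. LRRC2 overlaps TDGF1 on the opposite strand, so the level of LRRC2 may hold reads of TDGF1. ZFP42, a marker of pluripotent cells, was at 360 and 0.454 CPM, and PRDM14, a repressor of differentiation genes, at 79.3 and 0.0975 CPM. Their equal-weight NPC means were 4.04 and 0.725 CPM, with log2 ratios of −6.31 and −6.44.

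A second question was whether NPC carried a neural progenitor programme. PAX6 (ENSG00000007372.23, chromosome 11, 31784779 to 31817961), a transcription factor of the neuroectoderm, was at 419 CPM in NPC (416 to 422) and 0.580 CPM in iPSC (0.517 to 0.649), a log2 ratio of 9.50. SOX1, an early neural marker, was at 94.5 and 0.460 CPM. With equal weights the iPSC means were 15.04 CPM for PAX6 and 2.80 CPM for SOX1, and the log2 ratios 5.22 and 5.07. That PAX6 mean rests mostly on 3 iPSC with 100 CPM or more. They were at 355, 134 and 113 CPM and had totals of only 16898, 74468 and 407790 counts. The Notch effector HES5 was at 202 CPM in NPC against 0.0763 CPM in iPSC, or 203 against 4.77 CPM with equal weights. The intermediate filament gene VIM was at 1533 and 180 CPM, and NES at 790 and 275 CPM. DLK1, which encodes a Notch-like membrane protein, was at 1306 CPM in NPC and 2.96 CPM in iPSC, a log2 ratio of 8.79, or 6.79 with equal weights. Of 23 neural progenitor genes over the filter, 19 were at least 2-fold higher in NPC, 1 was lower and 3 lay within 2-fold. The lower one was ZIC2, at 32.6 CPM in NPC and 151 CPM in iPSC. The median log2 ratio was 4.96, above all 10000 random lists, and ran from 3.30 with equal weights to 6.48 without each gene's top cell. NES, at a log2 ratio of 1.52, lay within 2-fold once TMM scaling was used (0.78).

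**Figure D2:**
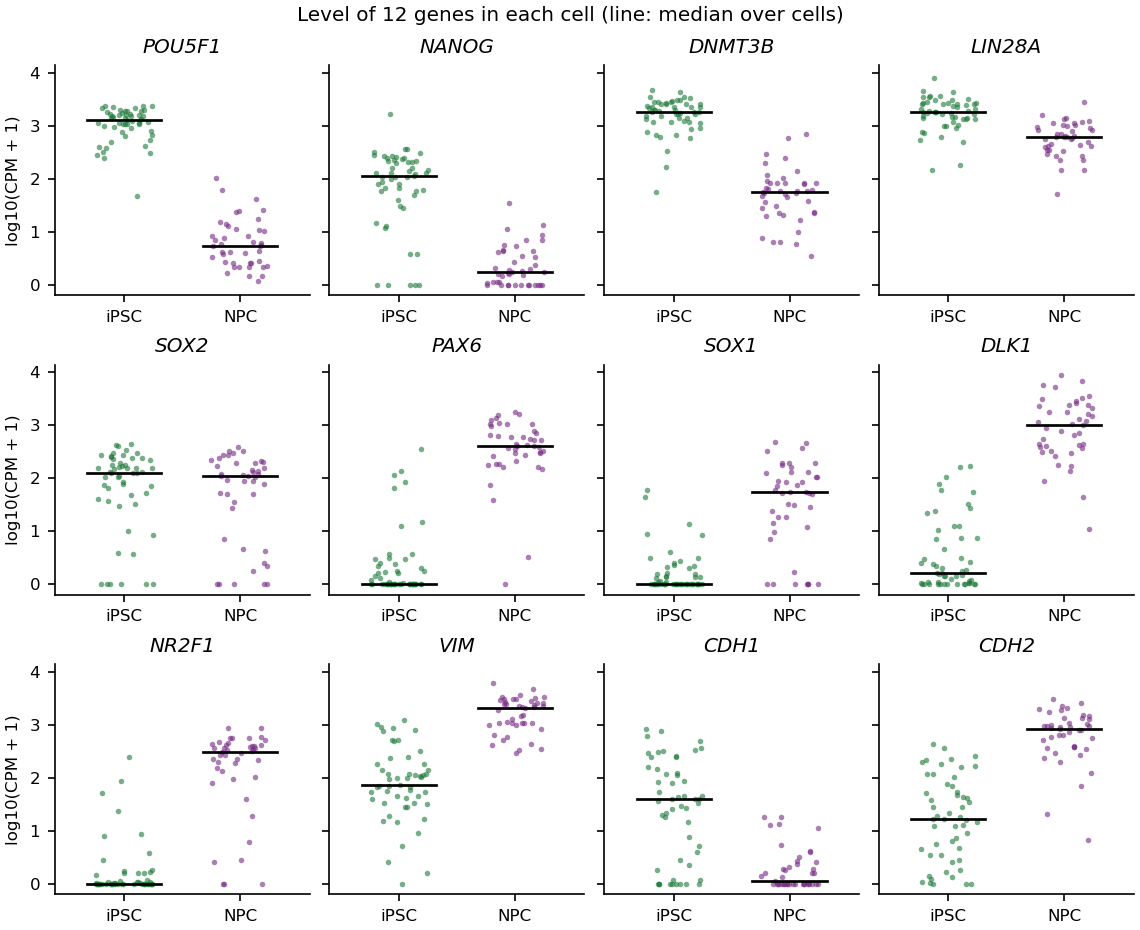
Level of 12 genes in each of 53 iPSC and 43 NPC, as log10(CPM + 1) per cell; the line marks the median over cells. POU5F1, NANOG, DNMT3B and CDH1 sit higher in iPSC, PAX6, SOX1, DLK1, NR2F1, VIM and CDH2 higher in NPC, and SOX2 overlaps, with a log2 ratio of −0.30 (−1.05 under TMM scaling).

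The regional genes of the NPC were mostly those of the forebrain. The rostral genes FEZF2, LHX2 and SIX3 stood at 85.3, 72.2 and 42.1 CPM in NPC and at 0.227, 0.206 and 0.773 CPM in iPSC. The log2 ratios of FEZF2 and LHX2, 8.55 and 8.45, were 6.28 and 6.93 with equal weights. OTX2, which marks forebrain and midbrain but is also read in pluripotent cells, was at 146 and 39.5 CPM. Of 15 forebrain genes, 13 were at least 2-fold higher in NPC and 2 were lower, EMX1 at 0.7999 against 8.71 CPM and HESX1 at 1.67 against 13.4 CPM. HESX1 was within 2-fold with equal weights, at a log2 ratio of 0.46. The median of the list was 6.59, above all 10000 random lists. It was 4.62 with equal weights, 8.09 without the deepest cell of each group and 9.65 without each gene's top cell. By the same rule applied to NPC, the protein-coding genes with the largest ratios towards NPC included NR2F1, FAM181A, BAHCC1, LIX1, HES5, NR2F2, NR2E1, ZEB2, MEIS2 and POU3F2, with log2 ratios from 9.68 to 11.84. NR2F1, an orphan nuclear receptor that patterns the cortex, was at 293 CPM in NPC and 0.0801 CPM in iPSC, and NR2E1, a regulator of neural stem cells, at 135 and 0.0668 CPM. With equal weights the log2 ratios of these genes were between 4.54 for ZEB2 and 6.91 for LIX1.

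Genes of more caudal regions were nearly unread. None of the 13 HOX genes on the hindbrain and spinal cord list reached 1 CPM in either group, and the highest in NPC was at 0.0927 CPM. Only 2 of the 17 genes on that list passed the filter, among them EGR2 at 3.33 CPM in NPC against 4.59 CPM in iPSC (log2 ratio −0.46, or −1.72 with equal weights), with a median of 0.29 that became −0.46 under TMM scaling. Of 9 midbrain genes only FGF8 passed, at 2.22 CPM in NPC and 2.56 CPM in iPSC, a log2 ratio of −0.21 that ran from −1.48 with equal weights to 0.85 over all alternatives. On the eye field list 5 of 6 genes were higher in NPC, or 4 of 6 under TMM scaling, with a median of 3.62, or 2.88 with equal weights and from 1.79 to 5.53 over all alternatives. Most were low: RAX, which specifies the eye field, was at 5.20 CPM in NPC, and VAX1 at 2.84 CPM, or 12.9 CPM with equal weights. The pigment cell gene PMEL was at 185 CPM in NPC against 61.3 CPM in iPSC. The log2 ratios of PMEL and RAX, 1.595 and 3.84, were 2.58 and 2.88 with equal weights.

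Markers of other lineages were compared in the same way, since an induction can leave other cells. The neural crest genes FOXD3 and ETS1 were lower in NPC, at 0.0488 against 21.9 CPM and at 0.488 against 59.9 CPM. Their log2 ratios of −8.81 and −6.94 were −7.31 and −2.81 with equal weights. On that list 1 of 6 genes was higher and 2 were lower, or 4 lower under TMM scaling or with equal weights, with a median of −0.49, or −2.02 with equal weights. The higher gene was TFAP2A, at a log2 ratio of 4.61, or 3.28 with equal weights and from 1.13 to 8.03 over all alternatives. Among 13 neuronal genes 8 were higher and 1 was lower, or 7 and 3 under TMM scaling, with a median of 2.62, or 1.56 with equal weights. DCX, which labels migrating neuroblasts, was at 110 CPM in NPC and 13.9 CPM in iPSC, and ELAVL4 at 21.4 and 1.24 CPM. For DCX the log2 ratio was 2.99, or 3.58 with equal weights. RBFOX3, which encodes the NeuN antigen of mature neurons, was at 2.76 CPM in NPC and 21.97 CPM in iPSC. Of 5 glial genes 2 were higher and 2 lower, with the myelin gene MBP at 2.46 CPM in NPC and 19.2 CPM in iPSC. Under TMM scaling 2 were higher and 3 lower, and with equal weights 3 higher and 1 lower. Their median was −0.27, or 1.11 with equal weights.

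Mesoderm and endoderm genes were low in NPC. Of 11 mesoderm genes 3 passed the filter, with KDR, a receptor for VEGF, at 1.28 CPM in NPC and 56.6 CPM in iPSC, and with TBX6 and MIXL1 under 2 CPM in both groups. The log2 ratio of KDR was −5.46, or −3.89 with equal weights. The median of the 3 was 0.07. Of 9 endoderm genes 3 passed, 1 higher and 2 lower, with a median of −3.76. Equal weights left 0 higher and 1 lower, with a median of −0.18. Among them AFP was at 0.210 CPM in NPC and 5.96 CPM in iPSC, a log2 ratio of −4.83, or −1.88 with equal weights. Of the 3 surface ectoderm genes over the filter 2 were lower and 1 higher, with a median of −1.60. TFAP2C was at 2.75 CPM in NPC and 8.30 CPM in iPSC, but its direction turned in another setting, with log2 ratios from −7.56 to 0.66. DLX3, the higher one, was at 1.05 CPM in NPC and had 2 reads in iPSC, a log2 ratio of 8.10 (counting interval 6.23 to 11.16), or 3.12 with equal weights. Of 6 mesenchymal genes 3 were higher in NPC and 1 was lower, with a median of 1.76, or 0.78 with equal weights. The higher 3 included LUM and COL3A1, for which 1 NPC held 49.7% and 1 NPC held 92.0% of the NPC reads. LUM had 1 read in iPSC, with a log2 ratio of 11.41 (counting interval 8.93 to 16.71), or 2.93 with equal weights. The log2 ratio of COL3A1, 7.19, was 1.33 with equal weights and −0.54 with thinned cells, so it has no settled direction. The smooth muscle actin gene ACTA2 was at 12.5 CPM in NPC and 1.51 CPM in iPSC, and the collagen gene COL1A1 at 22.5 and 90.9 CPM. Their log2 ratios of 3.05 and −2.01 were 3.85 and −1.04 with equal weights.

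**Figure D3:**
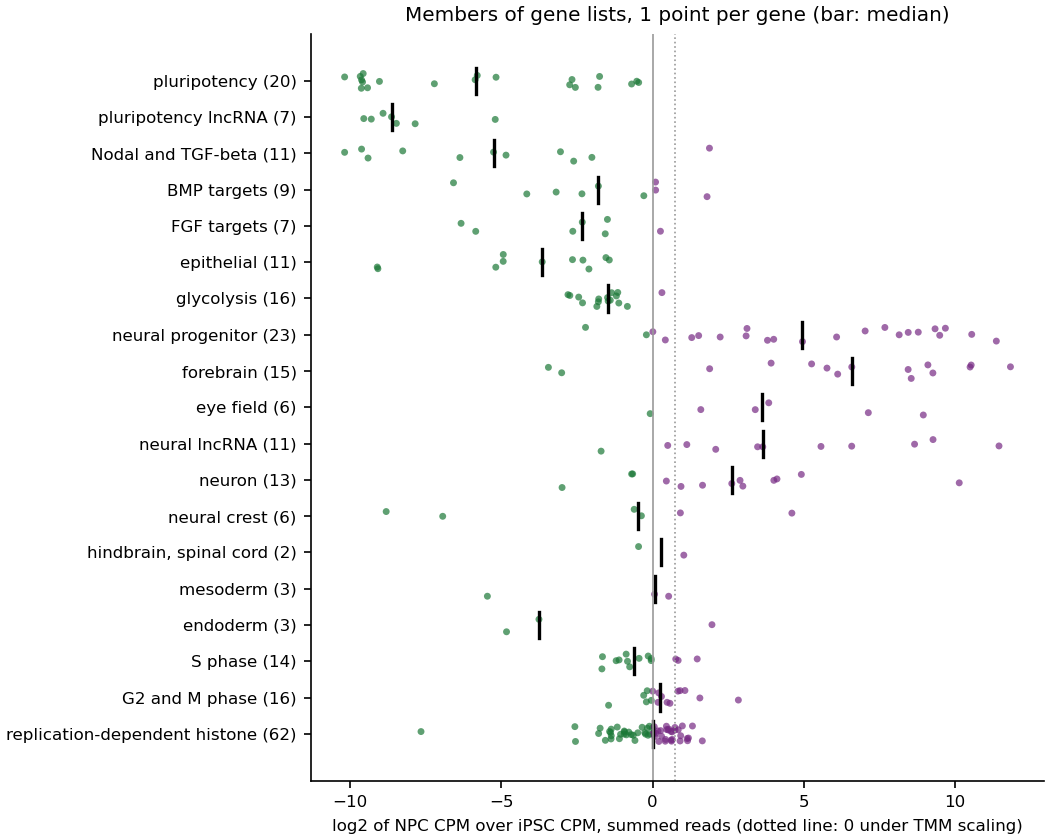
Log2 ratio of NPC over iPSC for the members of 19 gene lists (x axis), 1 point per gene, with the number of genes in brackets and a bar at the median; the dotted line marks 0 under TMM scaling. Medians ran from −8.63 for pluripotency lncRNA to 6.59 for forebrain genes.

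Because the medium blocks SMAD signalling, targets of the BMP and Nodal branches were examined. ID1 and ID3, direct BMP targets that inhibit differentiation factors, were at 1.07 and 3.23 CPM in NPC against 103 and 57.8 CPM in iPSC, log2 ratios of −6.58 and −4.16. The feedback inhibitor SMAD7 was at 3.80 and 34.7 CPM, a log2 ratio of −3.19. Equal weights gave −4.97 for ID1 and −2.26 for SMAD7. Of 9 BMP targets 5 were lower in NPC and 1 was higher, or 6 and 1 under TMM scaling, and SMAD6, SMAD9 and ATOH8 lay within 2-fold. Equal weights put SMAD9 and ATOH8 lower as well, at −1.19 and −1.33. The median was −1.79, from −2.76 to −1.04 over all alternatives, and 1 of 10000 random lists was as low. The Nodal antagonists LEFTY1 and LEFTY2 were at 1.37 and 1.20 CPM in NPC and at 113 and 34.4 CPM in iPSC. One iPSC held 58.4% of the iPSC reads of LEFTY1, and its log2 ratio of −6.37 ran from −7.72 to −5.01 over all alternatives, the latter with equal weights. The log2 ratio of LEFTY2, −4.85, ran more widely, from −9.18 to −3.44. Of 11 genes on the Nodal and TGF-beta target list 10 were lower, with a median of −5.26, from −7.54 to −2.59 over all alternatives. Of 10000 random lists 0 were as low. The exception was CCN2, a target of TGF-beta and of YAP, at 463 CPM in NPC and 126 CPM in iPSC, a log2 ratio of 1.88, or 1.26 with equal weights. With equal weights 8 of 10 were lower and 2 higher. GDF3 and the co-receptor gene TDGF1 on this list are also on the pluripotency list, so these 2 lists are not separate evidence.

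Other signalling targets differed by pathway. Of 7 FGF and ERK targets 6 were lower in NPC, with a median of −2.32, or −3.10 with equal weights, and 0 of 10000 random lists as low. SPRY4 was at 2.92 CPM in NPC and 235 CPM in iPSC, and ETV4 at 2.11 and 121 CPM. Of 6 Wnt targets 3 were higher, or 4 with equal weights, where NKD1 joined them with a log2 ratio of 1.65 in place of 0.44. The 3 by summed reads were LEF1 at 52.95 against 0.269 CPM, LGR5 at 42.1 against 0.240 CPM and TNFRSF19 at 7.92 against 0.330 CPM in NPC and iPSC, whereas AXIN2 was at 19.7 against 24.9 CPM. Under TMM scaling 3 were higher and AXIN2 was lower, at a log2 ratio of −1.09. Equal weights gave log2 ratios of 5.11 for LEF1, 3.29 for LGR5, 3.97 for TNFRSF19 and 0.25 for AXIN2, against 7.62, 7.45, 4.58 and −0.34 by summed reads. The list's median was 2.51, above 99.8% of random lists. Of 8 Notch genes 3 were higher, HES5, the ligand JAG1 at 579 against 29.7 CPM and the ligand DLL1 at 66.7 against 1.82 CPM, and DLL3 was lower at 1.46 against 8.66 CPM. By summed reads the log2 ratios of JAG1, DLL1 and DLL3 were 4.29, 5.20 and −2.57, and with equal weights 3.25, 6.24 and −1.87. Equal weights also put HEY1 lower, at −2.17 in place of 0.36. The median was 0.82, at percentile 87.5 of random lists, and −0.05 with DESeq2 size factors. In the hedgehog list GLI3 and PTCH1 were higher, at 520 against 86.1 CPM and 252 against 59.7 CPM, and GLI1 was lower at 0.0488 against 27.7 CPM. The log2 ratios of PTCH1 and GLI1, 2.08 and −9.15, were 1.36 and −6.70 with equal weights. Of the 5 hedgehog genes 2 were higher and 2 lower, or 2 and 3 under TMM scaling and 3 and 2 with equal weights, and the median of −0.65 was 1.36 with equal weights.

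Epithelial genes were lower in NPC. CDH1, the E-cadherin gene, was at 0.312 CPM in NPC (0.240 to 0.399) and 172 CPM in iPSC (171 to 173), a log2 ratio of −9.10. Weighting cells equally gave 2.15 and 122 CPM, a log2 ratio of −5.82. CDH2, the N-cadherin gene, was at 977 and 60.8 CPM, a ratio of 4.01. All 11 epithelial genes were at least 2-fold lower in NPC by summed reads, among them the splicing regulator ESRP1 at 0.239 against 130 CPM, EPCAM at 1.90 against 58.1 CPM, CLDN6 at 10.1 against 309 CPM and KRT18 at 43.05 against 212 CPM. The median was −3.65, with 0 of 10000 random lists as low. The log2 ratios of ESRP1 and EPCAM, −9.08 and −4.94, were −5.75 and −6.42 with equal weights. DSP, the desmoplakin gene, lay within 2-fold with equal weights, at −0.07.

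Glycolytic genes were lower in NPC as a list. LDHA, which makes lactate, was at 41.8 CPM in NPC and 279 CPM in iPSC, HK2 at 34.2 and 238 CPM, and PGAM1 at 144 and 716 CPM. Of 16 genes 14 were at least 2-fold lower, or 13 with equal weights, and 0 were higher, with a median of −1.48 and 0 of 10000 random lists as low. PKM and the glucose transporter gene SLC2A1 lay within 2-fold, and under TMM scaling PKM was lower too, at −1.58. Nuclear genes of oxidative phosphorylation had a median of −0.46, with 2 of 11 lower, or 3 with equal weights and 6 under TMM scaling. The 13 mitochondrially encoded mRNAs had a median of 0.44 by summed reads, −0.61 with equal weights and −0.31 under TMM scaling, so no direction holds for them.

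Cell cycle genes differed less, and the sign of the mitotic list depended on the setting. Of 14 S phase genes 4 were lower and 1 higher, or 8 and 0 under TMM scaling and 5 and 3 with equal weights. Their median was −0.60, at percentile 3.22 of random lists. The replicative helicase genes MCM5 and MCM4 were at 178 and 286 CPM in NPC and 568 and 659 CPM in iPSC. Of 16 mitotic genes 3 were higher and 1 lower, with a median of 0.25, at percentile 88.1 of random lists. Under TMM scaling 1 was higher and 2 lower, with a median of −0.50, and with equal weights 7 were higher and 0 lower, with a median of 0.81. HMGB2, a chromatin protein of dividing cells, was at 396 CPM in NPC and 55.4 CPM in iPSC, and kept a log2 ratio of 2.09 under TMM scaling. Replication-dependent histone mRNAs, which lack a poly(A) tail, were read in both groups. Of 62 over the filter 43 lay within 2-fold, 14 were lower and 5 higher, or 25 and 0 under TMM scaling and 24 and 1 with equal weights. Their median was 0.01, or −0.81 with equal weights. By summed reads it stood low against genes of their level, at percentile 2.3 of random lists. Histone copies share reads, so values of single genes, such as H1-1 at 0.0244 CPM in NPC and 4.92 CPM in iPSC (log2 ratio −7.66, or −5.61 with equal weights), are uncertain.

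Long noncoding RNAs also differed between the groups. All 7 pluripotency lncRNAs were lower in NPC, with a median of −8.63, or −6.31 with equal weights. ESRG, a primate-specific transcript of pluripotent cells, was at 1.11 CPM in NPC and 830 CPM in iPSC, or 12.4 and 976 CPM with equal weights. Among lncRNAs at 10 CPM or more and read in at least 50% of the cells of the higher group at 70000 reads, HPAT5, ESRG, LNCPRESS1, LINC02700 and LNCPRESS2 led towards iPSC, with log2 ratios from −9.61 to −9.17, or from −7.52 for HPAT5 to −5.59 for LNCPRESS1 with equal weights. EMX2OS, FEZF1-AS1, NR2F1-AS1, MALAT1 and CRNDE led towards NPC under the same rule by summed reads, with log2 ratios of 11.46, 7.74, 6.83, 4.90 and 3.95. Equal weights gave 8.93, 3.20, 3.01, 4.19 and 4.77 and so another order, with CRNDE and MALAT1 above FEZF1-AS1 and NR2F1-AS1. LHX5-AS1, read in 47.6% of NPC at that depth, fell outside the rule with a log2 ratio of 9.28, or 6.57 with equal weights. EMX2OS, FEZF1-AS1 and NR2F1-AS1 lie antisense to neural transcription factor genes and cannot be separated from them without strand. Of 11 neural lncRNAs 9 were higher, with a median of 3.64, or 2.93 with equal weights, and TUNAR was lower at 16.6 against 54.0 CPM. MALAT1, an abundant transcript of the nucleus, was at 8419 CPM in NPC (8407 to 8432) and 282 CPM in iPSC (280 to 283), a log2 ratio of 4.90. NEAT1, the scaffold of paraspeckles, was at 525 and 37.9 CPM, and the imprinted KCNQ1OT1 at 278 and 50.01 CPM. The snoRNA hosts GAS5 and SNHG1 lay within 2-fold, with GAS5 at a log2 ratio of −0.11, or −0.81 with equal weights. The list of 6 lncRNAs set beforehand as widely expressed had a median of 3.13, above all 10000 random lists. It includes CRNDE, which was read in only 4 of 48 iPSC and in 23 of 42 NPC at 70000 reads. With CRNDE on the list and GAS5 and SNHG1 within 2-fold, the median does not show a rise of widely expressed lncRNAs as a class.

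Clustering of all cells gave 7 groups, and none mixed iPSC with NPC. There were 4 clusters of 14, 13, 13 and 13 iPSC, and 3 clusters of 19, 13 and 11 NPC. NPC clustered alone gave 3 clusters of 17, 14 and 12 cells, whose median totals were 609166, 12344539 and 1664285 counts. No cluster had 3 fixed markers of a type among its 10 leading genes, so all remain unnamed. Across NPC, the first principal component correlated with log total counts at an absolute r of 0.779. The labels name no plates or library batches, but the titles give each cell a letter and a number, and 20 of these codes recur in both groups. If the codes are plate positions, the groups were on separate plates. No value within a batch could be had, and plate and group cannot be told apart. At 70000 reads per cell, POU5F1 was read in 48 of 48 iPSC (100%, interval 92.6 to 100) and in 14 of 42 NPC (33.3%, 19.6 to 49.5). PAX6 was read in 39 of 42 NPC (92.9%, 80.5 to 98.5) and 5 of 48 iPSC (10.4%, 3.47 to 22.7). With all reads, POU5F1 was read in all 43 NPC and PAX6 in 26 of 53 iPSC. Median genes detected per cell were 13043 in iPSC and 11263 in NPC, or 8602 and 7736 at 70000 reads.

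Total counts put the median of all 25411 genes over 1 CPM at a log2 ratio of 0.67. TMM scaling lowers each log2 ratio of summed reads by 0.75 and DESeq2 size factors by 0.87, so a positive summed ratio under those values turns negative. Neither was run on the ratios with equal weights. The medians of the pluripotency, neural progenitor, forebrain, eye field, BMP, Nodal and epithelial lists kept their sign under both.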

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

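The settings that left out the deepest cell of each group, or kept cells of at least 1000000 reads, were chosen after seeing the data; all others in this paragraph were planned. Median log2 ratios are given in the order pluripotency, neural progenitor, forebrain, eye field, hindbrain and spinal cord, BMP target, Nodal and TGF-beta target, epithelial and replication-dependent histone list. As reported they were −5.83, 4.96, 6.59, 3.62, 0.29, −1.79, −5.26, −3.65 and 0.01. With cells weighted equally they were −4.41, 3.30, 4.62, 2.88, 0.24, −1.52, −4.77, −3.90 and −0.81. With a library size that left out mitochondrial and ribosomal RNA genes they were −5.80, 4.99, 6.62, 3.65, 0.31, −1.76, −5.23, −3.62 and 0.03. With TMM scaling they were −6.58, 4.21, 5.84, 2.87, −0.46, −2.54, −6.01, −4.40 and −0.74. With DESeq2 size factors they were −6.70, 4.09, 5.72, 2.75, −0.58, −2.66, −6.12, −4.51 and −0.85. Without 11 shallow iPSC and 6 shallow NPC they were −5.83, 4.97, 6.60, 3.62, 0.29, −1.78, −5.25, −3.64 and 0.03. With cells thinned to 70000 reads they were −3.75, 4.26, 5.28, 3.47, −1.22, −1.56, −3.37, −4.45 and −0.84. With no filter on low genes they were −5.83, 4.48, 6.59, 3.40, 0.28, −1.04, −5.26, −3.65 and −0.045. With 1 CPM added to both groups they were −3.36, 4.54, 4.60, 1.79, 0.22, −1.61, −2.59, −3.03 and 0.01. Without each gene's top cell in each group they were −6.90, 6.48, 9.65, 5.53, 0.17, −2.48, −7.54, −3.99 and −0.19. Without the deepest cell of each group they were −5.61, 5.98, 8.09, 4.36, −0.38, −1.99, −6.37, −3.55 and 0.23. With equal weights among the 36 iPSC and 29 NPC of at least 1000000 reads they were −4.51, 5.56, 8.30, 4.67, 0.59, −1.99, −5.25, −3.92 and −0.54. With a filter of 10 CPM they were −6.54, 4.96, 8.45, 2.496, −2.76, −5.05, −3.65 and 0.02, with no value for the hindbrain and spinal cord list, which kept no gene. The sign held in every setting for 7 of these 9 lists, all but the hindbrain and spinal cord list and the replication-dependent histone list. The causes of these shifts were not tested, apart from TMM and DESeq2, which move every ratio by the same amount, −0.75 and −0.87.

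Of 148 named genes at least 2-fold apart, 139 kept their sign in all 10 alternatives and 117 stayed at least 2-fold apart in the same direction. The other 9 changed sign, in 17 of the 1468 values of the 148 genes, and the cause was not tested. Of the 17 named genes less than 2-fold apart, for which no direction is claimed, 9 changed sign in at least 1 alternative. With cells weighted equally the log2 ratio was 0.39 for PDGFRA, 2.16 for HHIP, −0.65 for MT-ND3 and −0.77 for FOS. With thinned cells it was 0.61 for PDGFRA, −1.39 for APOA1, −0.54 for COL3A1, 2.40 for HHIP, −0.92 for MT-ND3, 0.062 for CDC20 and −0.16 for FOS. Without each gene's top cell it was −1.04 for FOS and 0.92 for CDKN1A, and without the deepest cells −1.49 for FOS and 2.34 for CDKN1A. Among cells of at least 1000000 reads it was 0.66 for TFAP2C and −0.64 for MT-ND3.

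Genes specific to a group were chosen as at least 100-fold higher there, which largely sets their share in the other group. The share of the own level at which a group read the other group's specific genes was 1.05% in NPC and 1.57% in iPSC by summed reads. With equal weights it was 2.55% and 3.12%, and without the cell with the most of these reads 0.979% and 0.993%, both chosen after seeing the data.

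Median genes per cell were 11042 in iPSC and 9332 in NPC with at least 5 counts, and 8602 and 7736 at the thinned depth. Clustering all cells at resolution 0.5 gave 4 clusters in place of 7, and 500 variable genes gave 7, with no cluster mixing the groups in any setting. No paired analysis was possible because the labels name no cultures and the numbers only name cells. Depth limits what shallow cells can show: at 70000 reads, 1 read is worth 14.3 CPM, so a gene near that level is missed in many cells.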

Other observations

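Tests of the nuclear RNA share and of undifferentiated cells were written before their results were seen, and the others after. TET2, an enzyme that oxidises methylated DNA, was at 79.4 CPM in NPC and 2.75 CPM in iPSC, a log2 ratio of 4.85, opposite to DNMT3B. Of 7 DNA methylation genes 1 was higher and 1 lower, or 1 and 4 under TMM scaling, with a median of −0.35, or 0.35 with equal weights. Among 8 neural splicing regulators, NOVA1 was at 121 CPM in NPC and 14.9 CPM in iPSC, a log2 ratio of 3.02, or 4.12 with equal weights. On that list 2 were higher and 0 lower, or 1 and 1 under TMM scaling and 3 and 1 with equal weights. Its median of 0.53 was −0.21 under TMM scaling and 0.05 with equal weights. Of 8 histone genes with polyadenylated mRNA 3 were higher, or 4 with equal weights and 1 higher and 1 lower under TMM scaling, with a median of 0.36, or −0.39 under TMM scaling.

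Of 8 p53 targets 3 were lower and 1 higher, or 5 and 0 under TMM scaling and 2 and 0 with equal weights, with a median of −0.64. One iPSC held 94.4% of the iPSC reads of CDKN1A, whose log2 ratio of −1.73 was 2.34 without the deepest cells. Of 12 stress genes 3 were higher and 1 lower, or 1 and 2 under TMM scaling or with equal weights. The median of 0.40 was −0.35 under TMM scaling and 0.37 with equal weights. One NPC held 88.1% of the NPC reads of FOS, whose log2 ratio of 1.31 was −1.49 without the deepest cells, and 1 held 54.3% of those of EGR1. The 78 ribosomal protein genes had a median of −0.46, with 13 lower and 0 higher, or 59 lower under TMM scaling. Of 103 snoRNA genes 66 were higher and 7 lower, or 37 and 15 under TMM scaling and 60 and 12 with equal weights, with a median of 1.43 at percentile 4.75 of random lists, so they stood no higher than other genes of their level. At a threshold of 100 CPM, chosen after values were seen, DCX was reached in 17 of 43 NPC and 2 of 53 iPSC, and at least 2 of 6 neuronal genes in 4 NPC and 0 iPSC.

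MALAT1, NEAT1 and KCNQ1OT1 were higher in NPC. With equal weights, without each gene's top cell and without the deepest cell of each group, the lowest log2 ratio of the 3 genes was 2.60, which argues against a few cells as the source. By summed reads KCNQ1OT1 was at 2.47, and at 1.73 under TMM scaling. A larger share of nuclear RNA in the NPC libraries would raise TUG1, PVT1, LINC-PINT, DLEU2, MIR17HG, RPPH1 and RMRP alike. The highest of 3 medians over these 7 was 0.87, with equal weights. By summed reads their median was 0.56, against 3.79 for the 3 genes. The 3 genes were picked for their high ratios, however, so a lower median of other nuclear RNAs was likely in any case. The 7 also spread widely by summed reads, and DLEU2 at 3.34 lay above KCNQ1OT1. MIR17HG, LINC-PINT and TUG1 were at 1.85, 1.62 and 0.56, and RMRP, PVT1 and RPPH1 at −0.08, −0.90 and −1.18. The 7 were thus not raised alike, but for the 3 genes the test cannot settle the part of a larger nuclear share. A difference in these RNAs between the cell states and a difference between plates or library batches both stay open, untested.

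LIN28A, LIN28B, SALL4 and DPPA4 were read in NPC at 28.7%, 72.7%, 61.8% and 17.04% of their iPSC levels. Reads passed between libraries would leave them at the share of POU5F1, NANOG and TDGF1, which were at 0.145%, 0.673% and 0.127%, so the lowest value of 17.04% argues against this. Undifferentiated iPSC among the NPC would bring POU5F1 with them, yet the highest NPC cell held 8.18% of the iPSC mean. NANOG and TDGF1 each exceeded 10% of it in 1 NPC. A difference between the cell states in how these 4 genes are expressed stays open, untested.

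Protein-coding genes at 50 CPM or more in a group and at least 100-fold over the other were called specific to it. They were chosen in 1 subset of the cells and counted in the rest. The 100-fold limit largely sets how low their share in the other group is, so the shares measure no general background. Each group held reads of genes specific to the other, by summed reads 1.05% of the own level for iPSC genes in NPC and 1.57% for NPC genes in iPSC. One iPSC held 49.8% of these reads in iPSC and 1 NPC 21.2% of those in NPC. Without these 2 cells the shares were 0.979% and 0.993%, and with equal weights 2.55% and 3.12%, all chosen after the data were seen. Such reads were denser in shallow cells, with medians of 155 against 55.5 CPM in NPC and 246 against 26.1 CPM in iPSC under and over 1000000 reads. If cells made these transcripts, reads would grow in proportion to depth, and reads passed between libraries would depend on it weakly. The log10 slopes on depth were 0.645 in NPC (upper limit 0.8001) and 0.634 in iPSC (upper limit 0.842), against 0.946 and 1.04 for other genes of the same low level. Both upper limits lay under 1, which argues against own expression in proportion to depth as the only source in these cells. In iPSC the limits also lay under those of the other genes of the same level, whereas in NPC they overlapped. Neither upper limit fell below 0.8, the bound set after the data were seen. The parts of own expression and of reads passed between libraries therefore cannot be told apart for either set of genes. Low shares of cells, such as PAX6 in iPSC, may hold either, and other sources were not examined.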
